A study of Rattus norvegicus with 46 samples.

How the data were processed

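Rat skin was profiled on Clariom S arrays, 1 colour per array, with 46 arrays from 9 rats that were biopsied repeatedly. Per the labels, 5 mm punches of abdominal skin were taken on day -10 (baseline) and on days -4, 1, 3, 7 and 14. Vehicle (DMSO) or RTA-408 was injected on days -7, -5, -3 and 0. Radiation was 6 MeV electrons, 40 Gy in 4 fractions of 10 Gy, every other day over 8 days. RNA (100 ng, mean RNA integrity number 7.15) was used per the labels to make biotin-labelled cDNA, of which 2.5 ug was hybridized. The deposited table holds 1 log2 signal per feature and array, made by the authors and normalized between arrays by a method that is not given in the sources used here. The deposited signals reach 19.66 to 19.93, above the 16 that an unstretched 16-bit scanner value can give, so the scale is wider than that of raw intensities. Differences are therefore given as log2 differences on the deposited scale and not as folds. No further normalization was applied. Of 24834 features, 1646 controls were left out and 23188 were tested. Gene symbols came from the annotation supplied for the array, which gave 15049 features 1 symbol and 8139 none. The raw scans were not analysed here.

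Arrays were grouped by arm and day into 16 groups. For the unirradiated array of day 1, replicate 2, the title and source name day 1 while a description names day 3, and the title was followed. Before the data were examined, 6 comparisons were fixed for each of the 5 days: RTA-408 against vehicle in irradiated skin, irradiated against unirradiated vehicle skin, each of the 3 arms against baseline, and irradiated RTA-408 against unirradiated vehicle skin. The gene lists, the threshold, the rule for naming genes and the alternatives not called added below were fixed at the same time. A linear model with 1 mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3, with moderated variances and 30 residual degrees of freedom. Values of p were adjusted by Benjamini-Hochberg over the features of a comparison and day, and a feature was called at an adjusted p under 0.05. Changes of an effect over the 5 days were tested with the moderated F-test. The mean of the 5 days was compared between rats, with 3 rats per arm. SD is given within groups and SE is that of the model.

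The 38 gene lists of skin cell types and pathways, with 660 of 794 entries measured, were tested with camera at a preset correlation of 0.01 and adjusted over lists and days of a comparison. The same test with a correlation estimated for each list was an alternative. A list is described as called by the preset correlation, and its p with an estimated correlation stands beside it. Counts of list members used the adjustment over all features, and the adjustment over the list alone where so stated. A group was at the level of the negative controls if all its arrays were at or below the median of the 1153 negative control features of the array. The difference is then counted from that median and given as "at least". After the data were seen, the same was done for a group whose mean was at or below the mean of these medians, with each array set to its median or its signal, whichever was higher.

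A rule set which genes could be named, and those in the text were taken from these after the values were seen, so not every eligible gene is named. In each comparison and day, among called features with 1 symbol and no overlap between the arrays of both groups, eligible were the 3 highest and 3 lowest differences for the drug and radiation comparisons, and the 2 highest and 2 lowest for the others. Where none was called, the 2 highest and 2 lowest by smallest unadjusted p were eligible and named as not passing. A fixed panel was Nqo1, Hmox1, Gclc, Gclm, Txnrd1, Srxn1, Cdkn1a, Mdm2, Il1b, Il6, Tgfb1 and Col1a1. Of each list, up to 4 called members with the largest differences were eligible, or up to 2 with the smallest unadjusted p for a called list without such members. Genes with locus-type symbols were not named, and the brightest feature stood for a gene with several.

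Alternatives were quantile normalization before the fit, leaving out the 5797 dimmest features, array weights, the rat as a random block, the replicate number of the labels as a fixed block, a fit of the compared groups alone, leaving out each array in turn or each replicate number of an arm on all days (1 rat, except unirradiated replicate 2, which is rat 318 up to day 3 and rat 317 later, used for lists, changes over the days and the mean of the 5 days), and the estimated correlation for lists. The labelling batch was found from the spike-in features after the data were seen. Batch III had a dap spike-in signal of 10.85 to 11.37, above 9.77 to 10.12 in batch I and 9.90 to 10.52 in batch II. The ERCCmix2step35 spike-in parted batch I (9.383 to 9.985) from batch II (10.27 to 11.08). Added alternatives used the labelling batch as a block or compared arrays within a batch, and the test of lists between day -4 and later days was added then too. The fits were tested on simulated data of the size of these groups. For RTA-408 against vehicle, 48 and 88 percent of differences of 1 and 2 were called, and 10 of 174 calls were false. For irradiated against unirradiated vehicle it was 44 and 86 percent, with 10 of 170 calls false. These rates need not hold for the real arrays, where wrong splits of the irradiated rats called up to 104 features. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.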

Results

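Transcript levels were measured on 46 single-colour Clariom S arrays of abdominal skin biopsies from 9 Sprague-Dawley rats. The labels give a baseline biopsy on day -10 (6 arrays) and biopsies on days -4, 1, 3, 7 and 14 in each of 3 arms. The arms were irradiated skin with RTA-408 or with vehicle (3 arrays per day each) and unirradiated skin with vehicle (2 arrays per day). RTA-408 is a small-molecule activator of NRF2, the transcription factor that switches on antioxidant and detoxifying genes. The biopsies of day -4 were taken during the radiation course. Every difference below is one of mean deposited log2 values. Array medians lay between 6.84 and 6.95. Pairs of arrays within a group correlated across features with r between 0.927 and 0.990. Spike-in control features parted the arrays into 3 sets of 18 (I), 10 (II) and 18 (III), here called labelling batches. All baseline arrays were in batch I. Unirradiated arrays were in batch I on days -4 and 1 and in batch III later. Each irradiated arm had 1 array per day in batch II. A group whose arrays all lay at or below the median of the negative control features of the array, or did so on average, has no measurable signal as a group, and differences against it are given as "at least". The number of arrays limits the precision of every value.

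**Figure D1:**
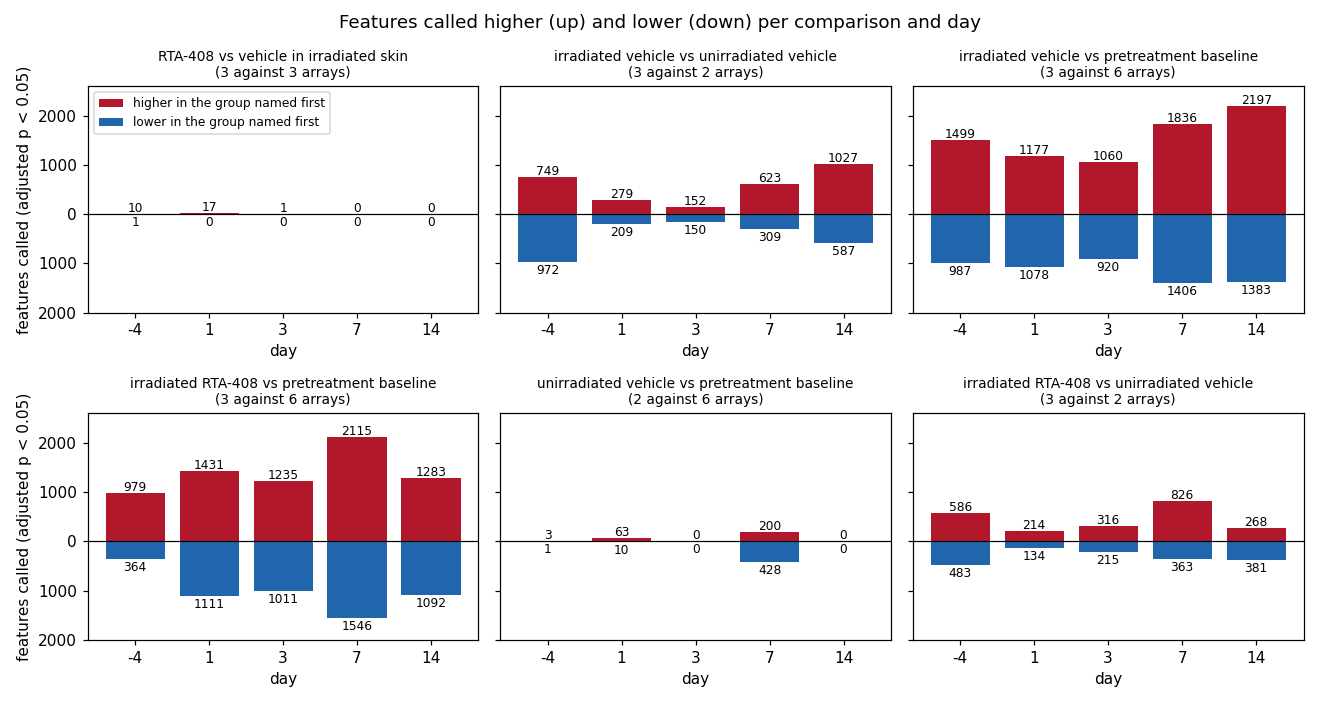
Bars give the number of features called at an adjusted p under 0.05 (vertical axis, higher upward and lower downward) on each day (horizontal axis). The panels of the 6 comparisons share 1 vertical scale. RTA-408 against vehicle reaches 17 features on day 1, and irradiated vehicle against baseline reaches 3580 on day 14.

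The drug comparison asked how RTA-408 changed irradiated skin relative to vehicle, with 3 rats against 3 on each day. On day -4, NRF2 targets were higher with RTA-408. Nqo1 (probe set TC1900000518.rn.2), a quinone reductase controlled by NRF2, averaged 13.04 ± 0.89 (SD, n = 3) with RTA-408 and 9.15 ± 0.29 (SD, n = 3) with vehicle, a difference of 3.88 ± 0.60 (SE; adjusted p = 0.00255). Akr1b8, an aldo-keto reductase, was higher by 3.31 ± 0.55 (SE; adjusted p = 0.00707) and Gstm1, a glutathione S-transferase, by 2.50 ± 0.39 (SE; adjusted p = 0.00255). Of the 37 measured NRF2 targets, 8 were higher, 0 lower and 29 did not pass, and 18 were higher when adjusted over the list alone. The list was higher by a mean of 1.03 (camera, adjusted p = 3.54e-33, and adjusted p = 2.24e-07 with an estimated correlation). Srxn1, which repairs oxidised peroxiredoxins, and Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, were higher by 2.06 and 1.98. Gclc, the catalytic subunit of that enzyme, differed by 1.99 and did not pass (adjusted p = 0.799), nor did the thioredoxin reductase Txnrd1 (1.15, adjusted p = 1) and the haem-degrading enzyme Hmox1 (0.84 ± 0.57, adjusted p = 1). In all, 10 features were called higher and 1 lower of 23188. Gsta1, Gstp1, Star and Osgin1, chosen after their values were seen, were among those higher, and the lower one has no symbol here.

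The calls of day -4 rested on few arrays. The count was 2 without RTA-408 replicate 1, 0 without RTA-408 replicate 2, 2 without vehicle replicate 1, 0 without vehicle replicate 2 and 7 without vehicle replicate 3. Nqo1 had an adjusted p of 0.117 without RTA-408 replicate 2 and of 0.0533 without vehicle replicate 2. For Gstm1 these values were 0.117 and 0.0533, with 0.0577 without vehicle replicate 1. Akr1b8 had 0.208, 0.117 and 0.0943 without RTA-408 replicates 1 and 2 and vehicle replicate 2. Srxn1 and Gclm kept their calls without RTA-408 replicate 3 and lost them without any other of the 6 arrays, with adjusted p up to 0.726 and 0.628. The NRF2 list kept its call without each rat in turn (highest adjusted p = 1.39e-22). Of 5 other lists called on day -4, with 0 members passing in each and adjusted p from 0.911 to 0.951 with an estimated correlation, macrophage and monocyte genes (mean difference 0.69, adjusted p = 3.9e-06) kept their call without each rat. Muscle genes differed by -1.49 (adjusted p = 0.0321) and by 1.41 without RTA-408 replicate 1, whose array of that day stood apart with a muscle list mean of 6.50 against 15.77 and 14.62 in replicates 2 and 3. Hair shaft keratin genes differed by 1.32 (adjusted p = 0.00169) and by -0.33 without that array (adjusted p = 0.97). Hypoxia and glycolysis genes (0.22, adjusted p = 0.0481) and immediate early genes (adjusted p = 0.0118) lost their calls without RTA-408 replicate 2 (0.528) and replicate 1 (0.131). A fit of the compared groups alone and a fit with the replicate number as a block called 0 features each. A fit blocked on labelling batch called 12 features, and within batch I 5 were called.

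On day 1, the day after the last injection, NRF2 targets were again higher with RTA-408. Aldh3a1, an aldehyde dehydrogenase abundant in epithelia, averaged 13.73 ± 0.35 (SD, n = 3) with RTA-408 and 8.77 ± 0.73 (SD, n = 3) with vehicle, a difference of 4.97 ± 0.72 (SE; adjusted p = 0.00043). Gstm1 averaged 14.24 ± 0.39 and 10.75 ± 0.30, a difference of 3.49 ± 0.39 (SE; adjusted p = 3.45e-06), and Nqo1 was higher by 3.77 ± 0.60 (SE; adjusted p = 0.00181). Adh7, an alcohol dehydrogenase that also oxidises retinol, was higher by 4.24 ± 0.84 (SE; adjusted p = 0.0281). The glutathione S-transferase Gsta1 was higher by 2.46 ± 0.41 (SE; adjusted p = 0.00398). The NRF2 list had 8 members higher, 0 lower and 29 not passing, with 20 higher when adjusted over the list alone, and a mean difference of 1.16 (camera, adjusted p = 3.95e-48, and adjusted p = 6.56e-09 with an estimated correlation). In all, 17 features were called higher and 0 lower. Other symbols among them, chosen after their values were seen, were Star, a mitochondrial cholesterol carrier (2.57 ± 0.35), Akr7a3, an aldehyde reductase (2.66 ± 0.39), and Tkt, an enzyme of the pentose phosphate pathway (1.76 ± 0.35). Sebaceous gland genes had a mean difference of 0.97 (0 of 15 passed; camera, adjusted p = 1.89e-06, and adjusted p = 0.723 with an estimated correlation), which was lost without RTA-408 replicate 2 (adjusted p = 0.481). Oxidative phosphorylation genes had a mean difference of -0.34 (0 of 24 passed; camera, adjusted p = 3.54e-06, and adjusted p = 0.947 with an estimated correlation), lost without vehicle replicate 3 (adjusted p = 0.196). Lists of cell division, T and NK cell, adipocyte and fatty acid and sterol synthesis genes were called too (0 members passing; camera, adjusted p from 0.000249 to 0.039, and adjusted p from 0.759 to 0.951 with an estimated correlation), and each lost its call without 1 or more of the rats.

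Aldh3a1 and Gstm1 kept their calls on day 1 without each array in turn (highest adjusted p 0.0114 and 0.000143). Adh7 lost its call without any 1 of the 6 arrays (adjusted p up to 0.358). Nqo1 missed the threshold without vehicle replicate 3 (adjusted p = 0.0601), and Gsta1 without RTA-408 replicate 1 (0.0892) and without vehicle replicate 3 (0.0604). The count was 8, 8 and 11 without RTA-408 replicates 1, 2 and 3, and 7, 8 and 5 without vehicle replicates 1, 2 and 3. With the compared groups alone 6 features were called, and with the replicate number as a block 1. Blocking on labelling batch gave 23 features, and within batch I 5 were called.

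**Figure D2:**
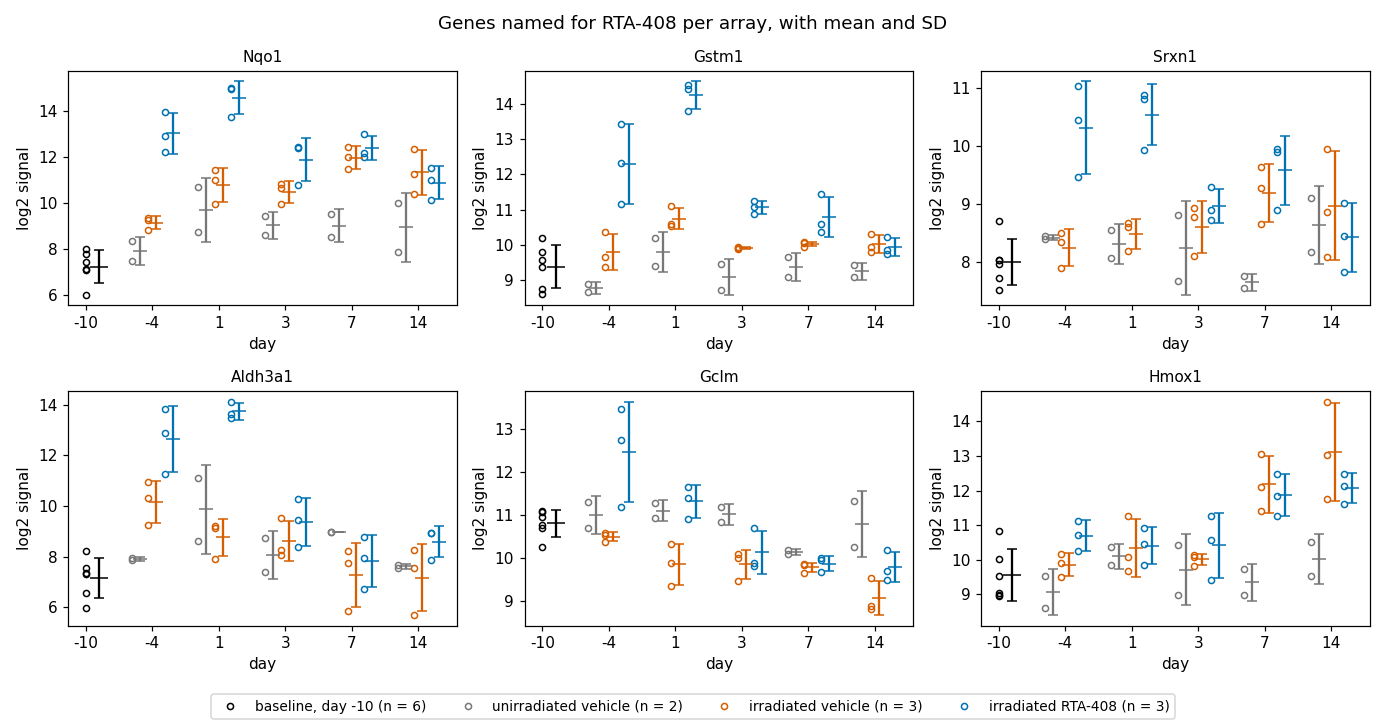
Each panel plots the log2 signal of a gene (vertical axis) against the day of the biopsy (horizontal axis, not to scale), with 1 circle per array and bars for mean and SD. Nqo1 with RTA-408 averages 14.57 on day 1 and 10.90 on day 14, against 7.25 at baseline.

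On day 3, the NRF2 list was higher with RTA-408, by a mean of 0.38, while 0 of its 37 members passed (camera, adjusted p = 4.13e-06, and adjusted p = 0.0711 with an estimated correlation). Nqo1 differed by 1.39 ± 0.60 (SE) and did not pass (adjusted p = 1). Gp2, a glycoprotein known from antigen-sampling epithelium and exocrine glands, was the only feature called. It averaged 6.27 ± 0.36 (SD, n = 3) with RTA-408, stayed at the level of the negative control features with vehicle, and was at least 0.12 higher (adjusted p = 5e-04). Macrophage and monocyte genes were higher by a mean of 1.12 (0 of 24 passed, 3 higher when adjusted over the list alone; camera, adjusted p = 1.85e-13, and adjusted p = 0.723 with an estimated correlation). Red blood cell genes were higher beside them (mean difference 1.10; camera, adjusted p = 0.000545, and adjusted p = 0.723 with an estimated correlation), a call lost without RTA-408 replicate 3 (0.726) and without vehicle replicate 3 (0.364). On the same day 10 other lists were called with 0 members passing (camera, adjusted p from 4.91e-05 to 0.0359, and adjusted p from 0.402 to 0.951 with an estimated correlation). Interferon response (0.53), matrix protease, inflammatory cytokine and chemokine, senescence and NADPH oxidase, fibroblast, Langerhans and dendritic cell, endothelium and pericyte and unfolded protein response genes had higher means and lost their calls without RTA-408 replicate 3 (adjusted p from 0.0506 to 0.576). Oxidative phosphorylation genes had a lower mean and lost their call without RTA-408 replicate 1 (0.817). Macrophage and monocyte genes (highest adjusted p = 1.03e-05) and antigen presentation genes (0.0338) kept their calls without each rat. With limma, 797 features had an unadjusted p under 0.05, against 1159 that chance alone gives. Without RTA-408 replicate 1 and without vehicle replicate 2 the count was 2. Blocking on labelling batch gave 1 feature, while 0 were called within batch III, in a fit of the compared groups alone and with the replicate number as a block.

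On day 7, interferon response genes were higher with RTA-408 by a mean of 1.33. Of the 23 measured, 0 passed over all genes and 12 were higher when adjusted over the list alone (camera, adjusted p = 2e-25, and adjusted p = 0.0711 with an estimated correlation). Usp18, an interferon-induced protease that removes ISG15, averaged 10.78 ± 0.19 (SD, n = 3) against 8.65 ± 0.31 (SD, n = 3), a difference of 2.14 ± 0.53 that did not pass (adjusted p = 0.944). Ifit1, an interferon-induced RNA-binding protein, was at the level of the negative control features with vehicle and at least 1.15 higher with RTA-408 (adjusted p = 0.403). Lists of T and NK cell, satellite cell and muscle regeneration, melanocyte and oxidative phosphorylation genes were called too, with 0 members passing (camera, adjusted p from 0.000166 to 0.0271, and adjusted p from 0.234 to 0.951 with an estimated correlation), and each lost its call without 1 or more of the rats. The NRF2 list had a mean difference of 0.12 (camera, adjusted p = 0.203). limma called 0 features, with 613 at an unadjusted p under 0.05 against 1159 by chance and a smallest adjusted p of 0.403. The alternatives called 0, apart from 2 without RTA-408 replicate 2.

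On day 14, genes of oxidative phosphorylation were higher with RTA-408 and genes of the unfolded protein response lower. The 24 measured oxidative phosphorylation genes differed by a mean of 0.74, with 0 passing over all genes and 15 higher when adjusted over the list alone (camera, adjusted p = 1.85e-13, and adjusted p = 0.723 with an estimated correlation). Skeletal muscle genes were higher beside them (0 of 23 passed, mean difference 1.65; camera, adjusted p = 0.0359, and 0.951 with an estimated correlation). This call was lost without vehicle replicates 1 (0.0505) and 3 (0.393) and without RTA-408 replicate 3 (0.0819). Muscle list means were 15.68 to 16.1 with RTA-408 and 12.32 to 15.38 with vehicle. At baseline both lists were lowest in replicate 2 and highest in replicate 4. The oxidative phosphorylation difference was thus not set apart from muscle content. Adipocyte genes were higher too (0 of 15 passed, mean difference 0.92; camera, adjusted p = 0.000141, and adjusted p = 0.745 with an estimated correlation), lost without irradiated vehicle replicate 3 (0.264). Cyc1, a subunit of complex III, averaged 11.83 ± 0.40 and 10.65 ± 0.26 (SD, n = 3 each), a difference of 1.17 ± 0.31 that did not pass (adjusted p = 0.183). The unfolded protein response list, of 16 genes, had a mean difference of -0.53, with 0 passing and 6 lower when adjusted over the list alone (camera, adjusted p = 3.54e-06, and adjusted p = 0.126 with an estimated correlation). Its members Pdia6, a disulfide isomerase, and Calr, a calcium-binding chaperone, differed by -0.86 and -0.69 (adjusted p = 0.18 each). The oxidative phosphorylation and unfolded protein response lists kept their calls without each rat in turn. Nqo1 averaged 10.90 ± 0.71 with RTA-408 and 11.34 ± 0.99 with vehicle (SD, n = 3 each), and the NRF2 list had a mean difference of -0.17 (camera, adjusted p = 0.238).

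Inflammatory and immune lists had lower means with RTA-408 on day 14, and these calls rested on irradiated vehicle replicate 3. Macrophage and monocyte genes differed by a mean of -1.43 (0 of 24 passed, 4 lower when adjusted over the list alone; camera, adjusted p = 1.54e-09, and adjusted p = 0.723 with an estimated correlation). The values were -1.06 for neutrophil genes (0 of 18, adjusted p = 0.0014) and -0.83 for T and NK cell genes (0 of 20, adjusted p = 7.6e-06), each with an adjusted p of 0.723 with an estimated correlation. In the array of irradiated vehicle replicate 3 the macrophage list mean was 13.86 and the neutrophil list mean 9.83. Without this rat the adjusted p values were 0.227, 0.756 and 0.528. Inflammatory cytokine and chemokine genes differed by a mean of -0.87 (0 of 24 passed; camera, adjusted p = 0.000498, and adjusted p = 0.88 with an estimated correlation; without this rat 0.259). Lists of NF-kB feedback, interferon response, antigen presentation, wound and stress keratinocyte, matrix protease, and senescence and NADPH oxidase genes were lower too (0 members passing; camera, adjusted p from 1.99e-05 to 0.0329, and adjusted p from 0.723 to 0.951 with an estimated correlation) and lost their calls without this rat (0.138 to 0.94). The haemoglobin scavenger receptor Cd163 averaged 10.63 ± 0.40 with RTA-408 and 14.21 ± 3.72 with vehicle (SD, n = 3 each; adjusted p = 0.193). limma called 0 features, with 2904 at an unadjusted p under 0.05 against 1159 by chance and a smallest adjusted p of 0.0565, that of Tmprss11d, an airway-type serine protease. The count was 1344 without vehicle replicate 1, 13 without vehicle replicate 2, 5 without RTA-408 replicate 3, 1 without RTA-408 replicate 1 and 0 without either of the others. It was 0 with the labelling batch as a block, 7 within batch III, 7 with array weights, and 1 both after renewed quantile normalization and without the dimmest features.

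**Figure D3:**
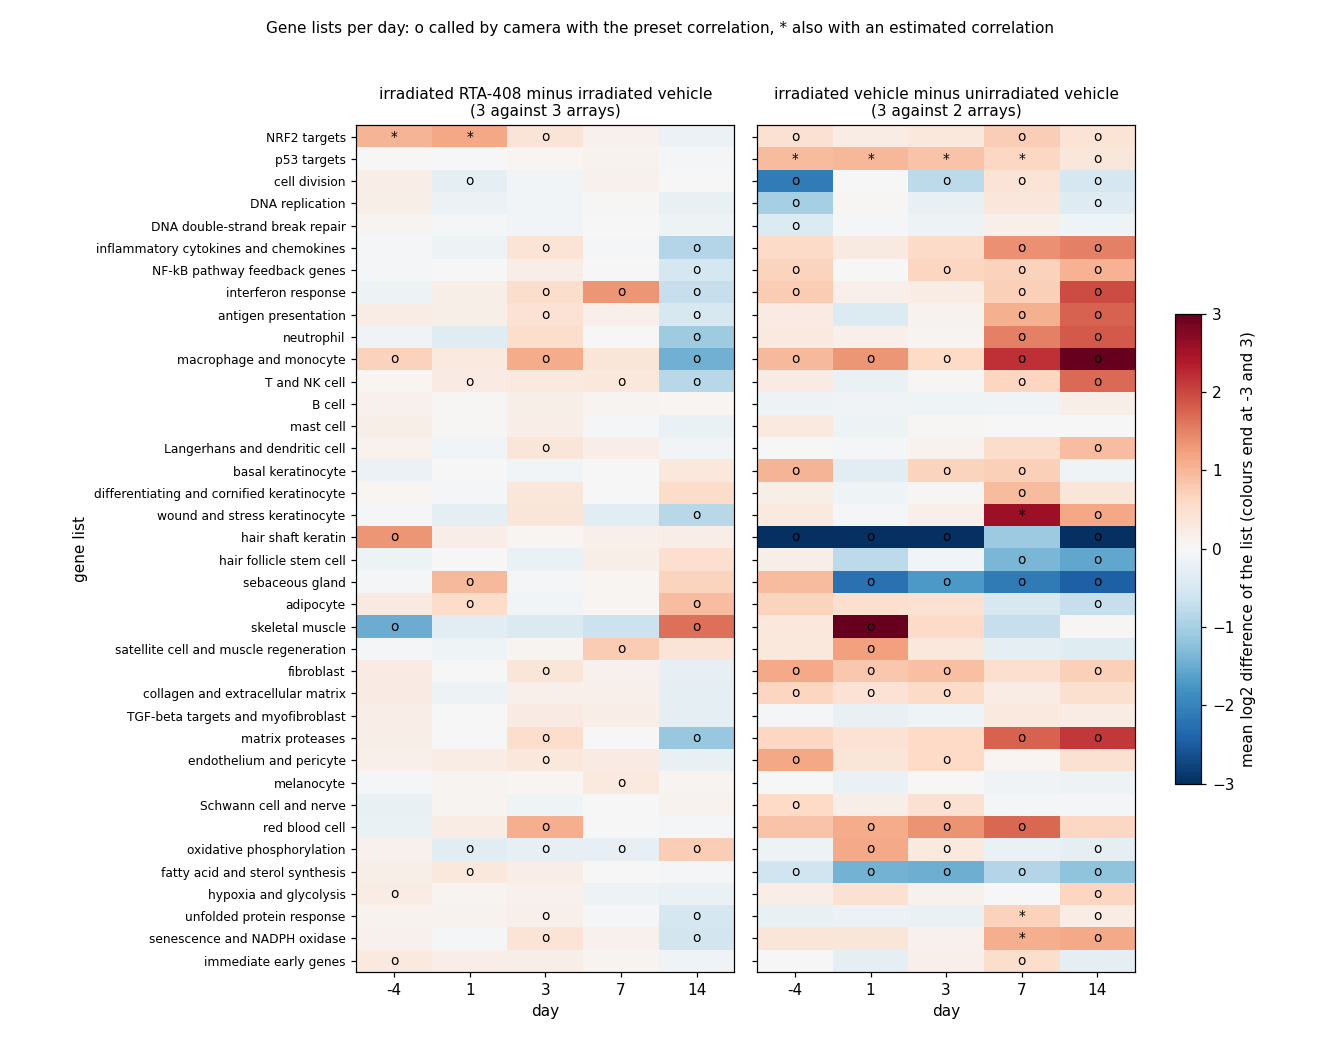
Colours give the mean log2 difference of 38 gene lists (vertical axis) on each day (horizontal axis) for RTA-408 against vehicle in irradiated skin (left) and irradiated against unirradiated vehicle skin (right), with colours ending at -3 and 3. The NRF2 list carries the mark for both correlations on days -4 and 1 on the left, and the p53 list on days -4 to 7 on the right.

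The p53 target list, with 27 measured genes, was called on 0 of the 5 days in the drug comparison, with adjusted p from 0.204 on day 7 to 0.991 on day -4. The redox genes Gclc, Txnrd1 and Hmox1, the p53 targets Mdm2 and Cdkn1a, the interleukins Il1b and Il6, the growth factor Tgfb1 and the collagen Col1a1 passed on no day. Averaged over the 5 days, Nqo1 was 12.56 ± 0.52 in the 3 rats given RTA-408 and 10.75 ± 0.24 in the 3 given vehicle, a difference of 1.81 ± 0.25 (SE) that did not pass (adjusted p = 0.392). limma called 0 features in these rat means, with 790 at an unadjusted p under 0.05. Alternatives gave 17 with the rat as a random block and 26 with the labelling batch as a block, and 0 without each rat in turn. The drug effect itself changed over the days for 3 features by the moderated F-test: Gp2 and Gstm1 (adjusted p = 0.0127 each) and Star (adjusted p = 0.0354). Gstm1 differed by 2.50, 3.49, 1.15, 0.77 and -0.07 on days -4, 1, 3, 7 and 14. Relative to day -4, the effect on the NRF2 list changed by -0.65 on day 3, -0.91 on day 7 and -1.20 on day 14 (camera, adjusted p = 1.89e-09, 1.43e-16 and 9.66e-15, and adjusted p = 0.00597, 0.000221 and 0.000325 with an estimated correlation). The count of 3 was 1 without RTA-408 replicate 2, 5 without RTA-408 replicate 3, 39 without vehicle replicate 1, 0 without vehicle replicate 2 and 1 without vehicle replicate 3.

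The radiation comparison set irradiated vehicle skin (n = 3) against unirradiated vehicle skin (n = 2) on each day. On day -4, targets of p53, the transcription factor activated by DNA damage, were higher in irradiated skin. Of 27 measured, 11 were higher, 0 lower and 16 did not pass, with 16 higher when adjusted over the list alone (mean difference 0.95; camera, adjusted p = 1.9e-10, and adjusted p = 0.00056 with an estimated correlation). Mdm2, the ubiquitin ligase that restrains p53, averaged 13.00 ± 0.39 (SD, n = 3) and 10.87 ± 0.01 (SD, n = 2), a difference of 2.14 ± 0.32 (SE; adjusted p = 0.00015). The drug efflux pump gene Abcb1b averaged 12.86 ± 0.33 (SD, n = 3), was at the level of the negative control features without radiation, and was at least 6.54 higher (adjusted p = 2.31e-12). The epoxide hydrolase Ephx1 was higher by 4.12 ± 0.45 (SE; adjusted p = 4.99e-07). Integrin Itgb4, which anchors basal keratinocytes, was higher by 2.77 ± 0.36 (SE; adjusted p = 1.22e-05), and 3 of 8 basal keratinocyte genes passed. Of 18 endothelium and pericyte genes, 7 were higher, 0 lower and 11 did not pass, with 10 higher when adjusted over the list alone (camera, adjusted p = 4.05e-08, and adjusted p = 0.143 with an estimated correlation).

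Cell division, DNA replication and hair shaft keratin genes were lower on day -4. Of 26 cell division genes, 20 were lower and 0 higher, and 25 lower over the list alone (mean difference -2.09, camera, adjusted p = 1.71e-21, and 0.157 with an estimated correlation). Mki67, a marker of cycling cells, averaged 10.19 ± 1.66 (SD, n = 3) and 13.87 ± 0.00 (SD, n = 2), a difference of -3.69 ± 0.82 (SE; adjusted p = 0.00616). Of 24 DNA replication genes 6 were lower and 0 higher, and 14 lower over the list alone (camera, adjusted p = 2.42e-09, and 0.261 with an estimated correlation). Of 19 hair shaft keratin genes 15 were lower and 0 higher, and 16 lower over the list alone (mean difference -6.59, camera, adjusted p = 3.58e-16, and 0.179 with an estimated correlation). The keratin-associated protein gene Krtap19-5 averaged 18.00 ± 0.72 without radiation (SD, n = 2), was at negative control level in irradiated skin, and at least 11.61 lower (adjusted p = 0.000241). In all, 749 features were higher and 972 lower. The count of 1721 was 707 and 972 without vehicle replicates 1 and 3, and 154 and 114 without unirradiated replicates 1 and 2. Mki67 lost its call without vehicle replicate 1 (adjusted p = 0.0526) and unirradiated replicates 1 (0.0777) and 2 (0.0787), while Mdm2, Abcb1b, Ephx1, Itgb4 and Krtap19-5 kept theirs without each. A fit blocked on labelling batch called 1285, and 666 within batch I.

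On days 1 and 3, p53 targets were higher and fatty acid and sterol synthesis genes lower. Of 27 p53 targets, 11 were higher on day 1 and 8 on day 3, with 0 lower and 16 and 19 not passing, and 18 and 14 were higher when adjusted over the list alone. Their mean differences were 1.00 and 0.86 (camera, adjusted p = 2.84e-14 and 3.67e-13, and adjusted p = 0.000107 and 0.000117 with an estimated correlation). Mdm2 was higher by 2.47 ± 0.32 on day 1 (SE; adjusted p = 2.06e-05) and by 1.95 ± 0.32 on day 3 (adjusted p = 0.000818). The cell cycle inhibitor Cdkn1a was higher by 2.62 ± 0.49 on day 1 (SE; adjusted p = 0.0043). Of 18 fatty acid and sterol synthesis genes, 4 were lower on day 1 and 3 on day 3, with 0 higher and 14 and 15 not passing, and 11 and 12 were lower when adjusted over the list alone. Their mean differences were -1.42 and -1.47 (camera, adjusted p = 4.18e-10 and 1.01e-13, and adjusted p = 0.179 and 0.129 with an estimated correlation). Sebaceous gland genes, whose cells make lipid, were lower beside them, with 2 of 15 lower, 0 higher and 13 not passing on day 1 and 0 of 15 passing on day 3, and 11 and 5 lower when adjusted over the list alone. Their mean differences were -2.23 and -1.72 (camera, adjusted p = 1.36e-07 and 6.37e-06, and adjusted p = 0.237 and 0.293 with an estimated correlation), and that of day 1 was -1.47 without unirradiated replicate 1. Insig1, a sterol sensor partner, differed by -3.09 ± 0.60 on day 3 (SE; adjusted p = 0.00462) and by -1.51 without unirradiated replicate 2. Hair shaft keratin genes had mean differences of -5.38 and -7.67 (2 and 11 of 19 lower; camera, adjusted p = 5.35e-12 and 9.15e-26, and adjusted p = 0.254 and 0.0845 with an estimated correlation), and that of day 1 was -3.25 without unirradiated replicate 2.

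On day 1, oxidative phosphorylation genes were higher as well. Of 24, 6 were higher, 0 lower and 18 did not pass, with 22 higher over the list alone. Their mean difference was 1.13 (camera, adjusted p = 2.02e-19, and 0.148 with an estimated correlation). Atp5po, a subunit of ATP synthase, was higher by 1.60 ± 0.26 (SE; adjusted p = 0.000706). Skeletal muscle genes had a mean difference of 5.01 beside them (0 of 23 passed; camera, adjusted p = 1.34e-09, and adjusted p = 0.361 with an estimated correlation), and the muscle list mean was 7.93 in unirradiated replicate 1 of that day and 15.52 in replicate 2. Without unirradiated replicate 1 the muscle call was lost (mean difference 1.21, adjusted p = 0.256). In all, 279 features were higher and 209 lower on day 1, and 152 and 150 on day 3. The count of 488 on day 1 was 214, 176 and 195 without vehicle replicates 1, 2 and 3, and 125 without unirradiated replicate 1. On day 3 the count of 302 was 185 and 151 without vehicle replicates 1 and 3, and 957 and 32 without unirradiated replicates 1 and 2. Cdkn1a on day 1 lost its call without unirradiated replicate 1 (adjusted p = 0.204), Mdm2 and Insig1 on day 3 without unirradiated replicate 2 (0.0938 and 0.727). The compared groups fitted alone gave 220 and 91 features and the replicate number as a block 187 and 78. The blocked fit on labelling batch called 495 and 379 features, and within a batch 79 (I, day 1) and 113 (III, day 3).

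On day 7, wound and stress keratinocyte genes were higher. Of 15 wound and stress keratinocyte genes 10 were higher, 0 lower and 5 did not pass, with 13 higher when adjusted over the list alone (mean difference 2.56; camera, adjusted p = 1.65e-15, and adjusted p = 0.0118 with an estimated correlation). Gpr15lg, an epithelial ligand that draws GPR15-bearing T cells, averaged 14.23 ± 0.90 (SD, n = 3), was at the level of the negative control features without radiation, and was at least 8.06 higher (adjusted p = 1.73e-06). The matrix protease Mmp3 was higher by 7.02 ± 1.24 (SE; adjusted p = 0.00115), the matrix protein Tnc by 5.31 ± 0.86, and Sprr1a, a cornified envelope precursor, by 3.91 ± 0.76 (adjusted p = 0.00294). S100a9, an alarmin of neutrophils and stressed keratinocytes, averaged 15.82 ± 0.46 (SD, n = 3) and 9.15 ± 1.49 (SD, n = 2), a difference of 6.68 ± 1.63 (adjusted p = 0.0149). Of 24 inflammatory cytokine and chemokine genes 4 were higher, 0 lower and 20 did not pass, with 7 higher when adjusted over the list alone (camera, adjusted p = 1.56e-05, and adjusted p = 0.304 with an estimated correlation). Of 16 unfolded protein response genes 7 were higher, 0 lower and 9 did not pass (camera, adjusted p = 1.14e-08, and adjusted p = 0.025 with an estimated correlation). Of 24 macrophage and monocyte genes 10 were higher, 0 lower and 14 did not pass (mean difference 2.19; camera, adjusted p = 1.08e-14, and adjusted p = 0.179 with an estimated correlation).

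The NRF2 list was higher on day 7 in vehicle-treated irradiated skin as well, with 7 of 37 higher, 0 lower and 30 not passing (camera, adjusted p = 0.00019, and adjusted p = 0.129 with an estimated correlation). Nqo1 was higher by 2.95 ± 0.67 (SE; adjusted p = 0.00971) and Akr1b8 by 4.35 ± 0.62 (adjusted p = 0.000117). The p53 list had 6 of 27 higher, 0 lower and 21 not passing (mean difference 0.63; camera, adjusted p = 2.53e-07, and adjusted p = 0.00642 with an estimated correlation). Sebaceous gland genes had a mean difference of -2.13, with 2 of 15 lower, 1 higher and 12 not passing (camera, adjusted p = 3.89e-06, and adjusted p = 0.293 with an estimated correlation). In all, 623 features were higher and 309 lower. The count of 932 was 245 without vehicle replicate 3, and 377 and 123 without unirradiated replicates 1 and 2. S100a9 lost its call without vehicle replicate 3 (adjusted p = 0.0521) and unirradiated replicate 2 (0.221), and Nqo1 without unirradiated replicate 2 (0.186). Hair shaft keratin genes had a mean difference of -1.08 and were not called (camera, adjusted p = 0.354), with list means of 5.42 to 5.53 in irradiated and of 5.65 and 7.49 in unirradiated arrays of that day. The blocked fit called 1245 features, and within batch III 124 were called.

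**Figure D4:**
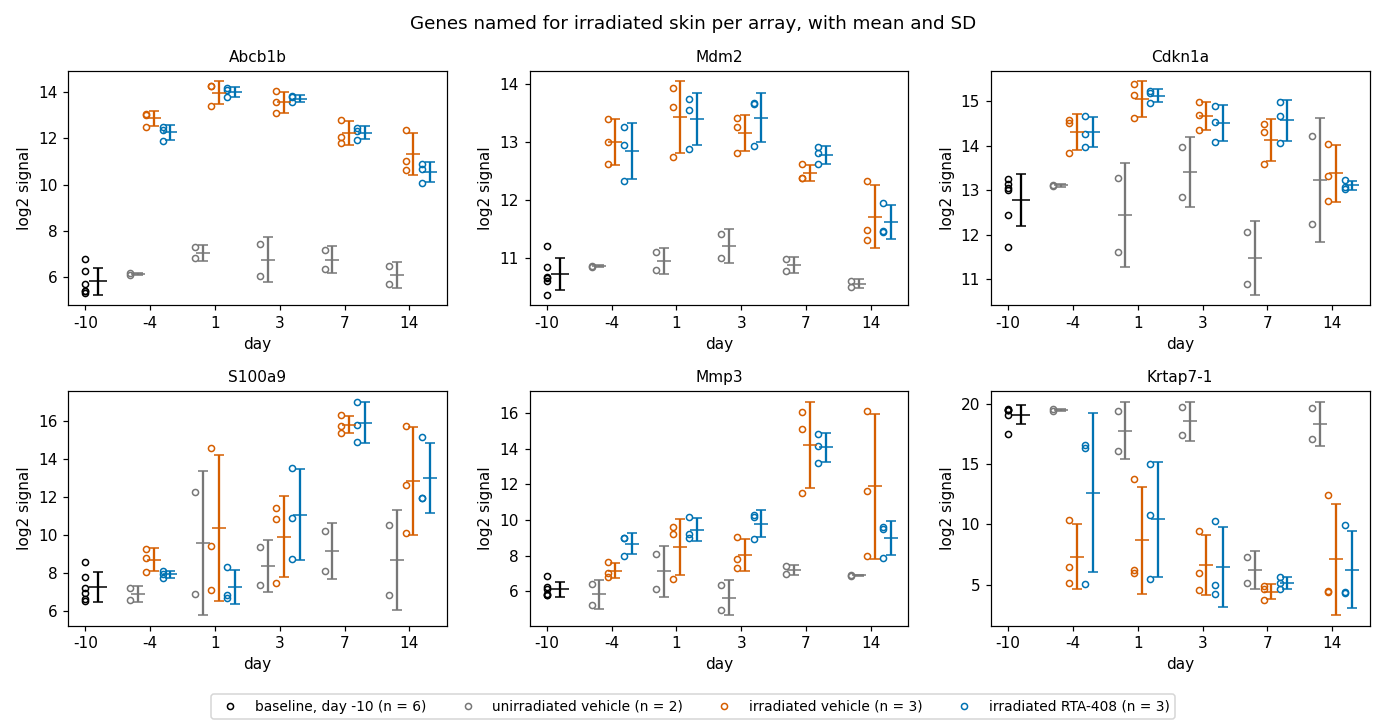
Each panel plots the log2 signal of a gene (vertical axis) against the day of the biopsy (horizontal axis, not to scale), with 1 circle per array and bars for mean and SD. Abcb1b averages 13.97 in irradiated vehicle skin on day 1 and 5.81 at baseline, while Krtap7-1 is low in unirradiated skin on day 7 too.

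On day 14, macrophage, T and NK cell, interferon response, antigen presentation and neutrophil genes were higher in irradiated vehicle skin. Of 24 macrophage and monocyte genes 21 were higher, 0 lower and 3 did not pass (mean difference 3.20; camera, adjusted p = 4.29e-24, and adjusted p = 0.0845 with an estimated correlation). Cybb, a subunit of the phagocyte NADPH oxidase, averaged 15.69 ± 2.30 (SD, n = 3) and 10.94 ± 0.38 (SD, n = 2), a difference of 4.76 ± 0.77 (SE; adjusted p = 0.000512). The antibody receptor Fcgr2b was higher by 4.93 ± 0.82 (SE; adjusted p = 0.000556). Of 20 T and NK cell genes 13 were higher, 0 lower and 7 did not pass, with 16 higher when adjusted over the list alone (camera, adjusted p = 8.73e-14, and adjusted p = 0.0845 with an estimated correlation). Of 23 interferon response genes 13 were higher, 0 lower and 10 did not pass, with 20 higher when adjusted over the list alone (camera, adjusted p = 5.25e-15, and adjusted p = 0.134 with an estimated correlation). Of 15 antigen presentation genes 8 were higher, 0 lower and 7 did not pass (camera, adjusted p = 3.49e-11, and adjusted p = 0.143 with an estimated correlation). RT1-DMa, which loads peptides onto class II molecules, was higher by 2.56 ± 0.54 (SE; adjusted p = 0.00364). Of 18 neutrophil genes 6 were higher, 0 lower and 12 did not pass (mean difference 1.85; camera, adjusted p = 2.25e-05, and adjusted p = 0.213 with an estimated correlation). Much of the size of these differences came from irradiated vehicle replicate 3. The macrophage list means were 9.68, 10.88 and 13.86 and the neutrophil list means 6.31, 7.29 and 9.83 in irradiated vehicle replicates 1, 2 and 3. Without replicate 3 the mean differences were 2.01 (macrophage and monocyte, 3.20 with it), 0.84 (neutrophil, 1.85), 0.97 (T and NK cell, 1.70), 1.09 (interferon response, 1.95) and 1.21 (antigen presentation, 1.77), with adjusted p of 1.16e-22, 0.00518, 5.05e-09, 8.86e-09 and 2.54e-08.

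Sebaceous gland and hair shaft keratin genes were lower on day 14. Of 15 sebaceous gland genes 6 were lower, 0 higher and 9 did not pass, with 9 lower when adjusted over the list alone (mean difference -2.44; camera, adjusted p = 2.53e-07, and adjusted p = 0.248 with an estimated correlation). Of 19 hair shaft keratin genes 11 were lower, 0 higher and 8 did not pass, with all 19 lower when adjusted over the list alone (camera, adjusted p = 4.43e-15, and adjusted p = 0.183 with an estimated correlation). The p53 list had 2 of 27 higher (mean difference 0.33; camera, adjusted p = 0.0145, and adjusted p = 0.213 with an estimated correlation), a call lost without vehicle replicate 1 (0.0623) and unirradiated replicate 2 (0.233). In all, 1027 features were higher and 587 lower. The count of 1614 was 2962 without vehicle replicate 1, 351 without vehicle replicate 3 and 98 without unirradiated replicate 1. RT1-DMa lost its call without unirradiated replicate 1 (adjusted p = 0.091), while Cybb, Fcgr2b and the macrophage, interferon and T and NK cell lists kept theirs without each. A fit of the compared groups alone called 0 features, so the day 14 calls rest on the spread of all groups. The replicate number as a block gave 26. A block on labelling batch gave 1973 features, and within batch III 1623 were called. The radiation effect changed over the days for 501 features by the moderated F-test, a count of 838, 156 and 74 without vehicle replicates 1, 2 and 3.

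**Figure D5:**
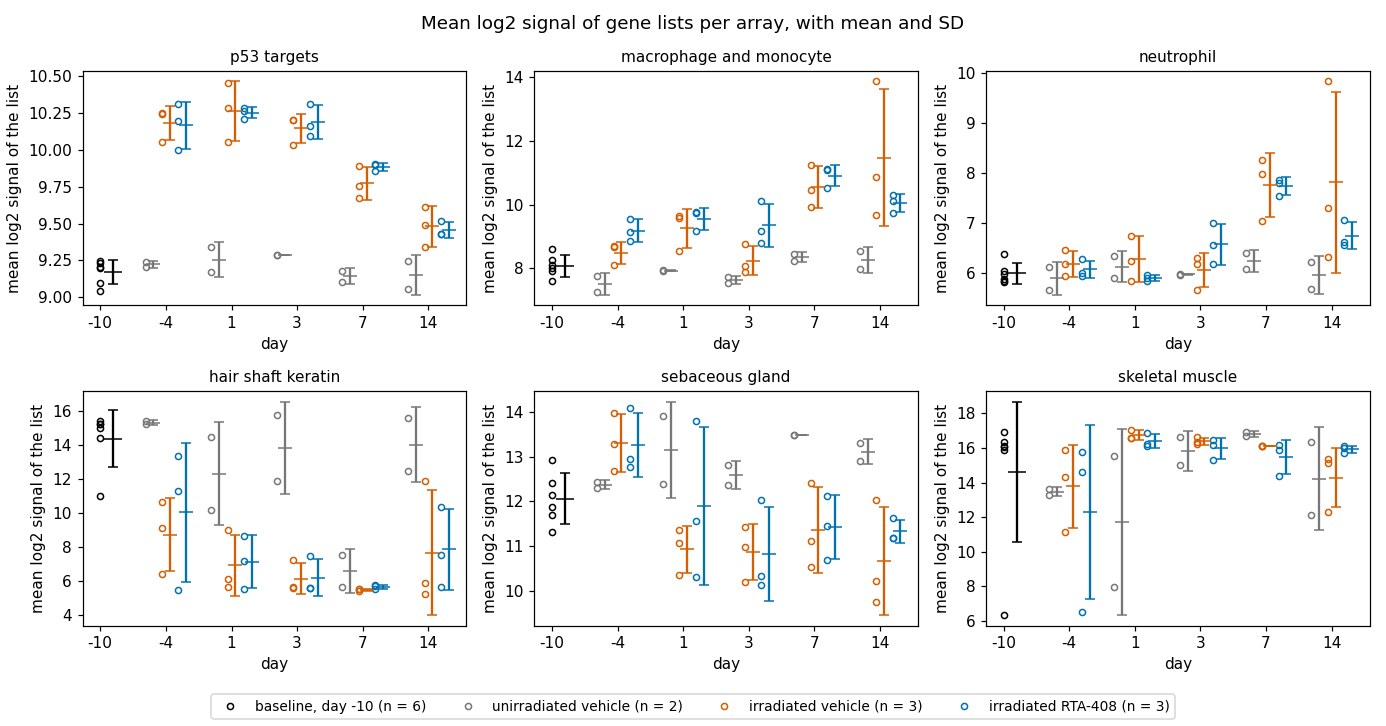
Each panel plots the mean log2 signal of a gene list (vertical axis) against the day of the biopsy (horizontal axis, not to scale), with 1 circle per array and bars for mean and SD over arrays. The p53 list lies at 9.04 to 9.34 in all unirradiated arrays, and the muscle list falls to 6.34 in 1 baseline array.

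Irradiated vehicle skin (n = 3 per day) was also set against the baseline biopsies (n = 6), which gives the change from the state before treatment. Abcb1b, at or below the median of the negative control features in 5 of 6 baseline arrays, was higher than at baseline by at least 6.56 on day -4, 7.67 on day 1 and 7.26 on day 3 (adjusted p = 2.37e-16, 2.26e-18 and 1.17e-17). Nqo1 rose on all 5 days, by 1.90, 3.55, 3.24, 4.72 and 4.09 in order of day, although on day -4 it lost its call without vehicle replicates 1 (adjusted p = 0.0879) and 3 (0.0614). In unirradiated skin Nqo1 differed from baseline by 0.68, 2.46, 1.78, 1.77 and 1.70, none passing (adjusted p = 0.781, 0.0565, 0.951, 0.103 and 1). Irradiated against unirradiated vehicle passed for Nqo1 on days 7 and 14 (2.95 and 2.38, adjusted p = 0.00971 and 0.0256; on day 14 it was 1.32 without unirradiated replicate 2, adjusted p = 0.428, and lost its call without vehicle replicates 2 and 3, 0.121 and 0.0964) and not on days -4, 1 and 3 (1.22, 1.09 and 1.46, adjusted p = 0.301, 0.458 and 0.322). The p53 list had 16, 18, 14, 9 and 6 of 27 genes higher on days -4, 1, 3, 7 and 14 (camera, adjusted p from 5.88e-17 on day 1 to 0.0109 on day 14, which became adjusted p = 0.177 with an estimated correlation on day 14). Cell division genes were lower on days -4, 1 and 3, with 19, 15 and 5 of 26 lower (camera, adjusted p = 2.04e-17, 8.24e-14 and 5.46e-11, and adjusted p = 0.18, 0.226 and 0.32 with an estimated correlation). On day 1 the mean difference was -1.29, and unirradiated skin differed from baseline by -1.29 as well, with no call for irradiated against unirradiated vehicle on that day (camera, adjusted p = 0.92). On day 7 Gpr15lg was at least 8.06 higher than at baseline (adjusted p = 2.1e-09) and Il36g, an epidermal interleukin of the IL-1 family, higher by 6.22 ± 0.67 (SE; adjusted p = 6.64e-08). Lgr5, a hair follicle stem cell marker, averaged 10.60 ± 0.76 at baseline (SD, n = 6), was at the level of the negative control features on day 7 and was at least 4.61 lower (adjusted p = 6.52e-05), which did not pass with the labelling batch as a block (adjusted p = 0.137). On day 14, Cd163 was higher by 6.02 ± 0.85 (SE; adjusted p = 6.09e-06; 3.97 without vehicle replicate 3) and the complement gene C1qb by 4.80 ± 0.68 (adjusted p = 5.69e-06), with 21 of 24 macrophage and monocyte genes higher (camera, adjusted p = 1.66e-24, and adjusted p = 0.087 with an estimated correlation).

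In this comparison, 1499 features were higher and 987 lower on day -4, 1177 and 1078 on day 1, 1060 and 920 on day 3, 1836 and 1406 on day 7, and 2197 and 1383 on day 14. With the labelling batch as a block the counts were 1851, 1852, 141, 518 and 560, and from day 3 on no array of these groups is in the batch of the baseline. Within batch I they were 986 on day -4 and 1312 on day 1. On day 14 a fit of the compared groups alone gave 856. Without vehicle replicates 1 and 3 the count of day -4 was 941 and 1599, and that of day 3 was 1258 and 1148. Without vehicle replicates 1, 2 and 3 that of day 1 was 1304, 1265 and 1412, and without replicate 3 those of days 7 and 14 were 1831 and 1594. Abcb1b, Gpr15lg, Il36g, Cd163 and C1qb kept their calls on the days named without each array.

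Irradiated skin with RTA-408 (n = 3 per day) against baseline (n = 6) gave NRF2 targets higher early. The list had 19 of 37 genes higher, 0 lower and 18 not passing on day -4, and 24 higher, 0 lower and 13 not passing on day 1 (camera, adjusted p = 3.51e-23 and 6.26e-23, and adjusted p = 6.91e-06 with an estimated correlation on both days). Nqo1 was higher by 5.78 ± 0.52 on day -4 (SE; adjusted p = 2.91e-09) and by 7.32 ± 0.52 on day 1 (adjusted p = 4e-12; 0.68 and 2.46 in unirradiated skin, not passing), where Akr1b8, at or below the median of the negative control features in 3 of 6 baseline arrays, was higher by at least 6.56 (adjusted p = 4e-12) and Gstm1 by 4.86 ± 0.33 (adjusted p = 3.13e-12). On day 7, 22 of 23 interferon response genes were higher, 0 lower and 1 did not pass (mean difference 2.71; camera, adjusted p = 6.26e-23, and adjusted p = 0.0526 with an estimated correlation). In unirradiated skin this list differed from baseline by 0.66 on that day (camera, adjusted p = 0.00497, and adjusted p = 0.863 with an estimated correlation), lost without unirradiated replicate 1 (0.9). Isg15, a ubiquitin-like protein induced by interferon, was at the level of the negative control features at baseline and at least 2.66 higher (adjusted p = 4.19e-07), and Usp18 was higher by 3.99 ± 0.46 (SE; adjusted p = 2.48e-07). On day 14 the cystatin Stfa3 was higher by 8.36 ± 0.88 (SE; adjusted p = 1.3e-07) and Casp14, a protease of terminal keratinocyte differentiation, by 4.36 ± 0.81 (adjusted p = 0.000425), with 6 of 10 differentiating and cornified keratinocyte genes higher (mean difference 1.84; camera, adjusted p = 6.6e-07, and adjusted p = 0.0957 with an estimated correlation). Unirradiated skin had these genes higher than baseline too (0 of 10 passed, mean difference 0.915; camera, adjusted p = 4.56e-05, and adjusted p = 0.467 with an estimated correlation). The p53 list had 17 of 27 genes higher on day -4 and 3 on day 14 (camera, adjusted p = 6.95e-18 and 0.0231, and adjusted p = 6.91e-06 and 0.244 with an estimated correlation).

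Here 979 features were higher and 364 lower on day -4, 1431 and 1111 on day 1, 1235 and 1011 on day 3, 2115 and 1546 on day 7, and 1283 and 1092 on day 14. Blocked on labelling batch, the counts were 931, 2177, 141, 763 and 246, and within batch I they were 284 on day -4 and 1772 on day 1. On day -4 a fit of the compared groups alone gave 552. On day -4 the count of 1343 was 847 and 894 without baseline replicates 1 and 3 and 331 without RTA-408 replicate 3. It was 1444 without RTA-408 replicate 1 on day 1, 1190 without replicate 3 on day 3, and 1405 and 1435 without replicates 1 and 2 on day 14. The p53 call of day 14 was lost without baseline replicate 4 (adjusted p = 0.0672) and RTA-408 replicate 1 (0.0621).

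Unirradiated vehicle skin (n = 2 per day) against baseline (n = 6) gives the background that repeated biopsy, vehicle and time bring without radiation. On day -4, 4 features were called, among them Per2, Dbp and Bmal1, while no list of clock genes was tested. Per2, a repressor of the circadian clock, was higher by 1.85 ± 0.29 (SE; adjusted p = 0.00505), Dbp, a clock output factor, by 2.59 ± 0.46 (adjusted p = 0.017), and the activator Bmal1 differed by -1.52 ± 0.25 (adjusted p = 0.00798). These calls rested on both unirradiated arrays. On day 1, Dbp was higher by 4.24 ± 0.46 (adjusted p = 1.64e-06), and 4 of 8 basal keratinocyte genes were higher, 0 lower and 4 did not pass (camera, adjusted p = 1e-06, and adjusted p = 0.23 with an estimated correlation). Cell division genes were lower on day 1 (0 of 26 passed, 18 lower when adjusted over the list alone, mean difference -1.29; camera, adjusted p = 1.04e-17, and adjusted p = 0.612 with an estimated correlation). On day 7, hair shaft keratin genes were lower, with 16 of 19 lower, 0 higher and 3 not passing, and all 19 lower when adjusted over the list alone (mean difference -7.80; camera, adjusted p = 4.34e-27, and adjusted p = 0.23 with an estimated correlation). Krtap1-5 averaged 18.12 ± 0.84 at baseline (SD, n = 6), was on average below the median of the negative control features on that day (1 of 2 arrays), and was at least 11.88 lower (adjusted p = 5.55e-05), which did not pass with the labelling batch as a block (adjusted p = 0.222). Sbk2, a kinase gene at or below the median of the negative control features in 5 of 6 baseline arrays, was at least 5.07 higher on day 7 (adjusted p = 5.55e-05), and sebaceous gland genes had a mean difference of 1.43 (0 of 15 passed; camera, adjusted p = 0.000848, and adjusted p = 0.797 with an estimated correlation). The p53 and NRF2 lists were called on 0 of the 5 days.

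In unirradiated skin, 3 features were higher and 1 lower on day -4, 63 and 10 on day 1, and 200 and 428 on day 7. limma called 0 on days 3 and 14, with 1058 and 984 at an unadjusted p under 0.05. With the labelling batch as a block the counts were 4, 114, 0, 4 and 0 in order of day, and within batch I they were 2 on day -4 and 10 on day 1. Fitted alone, the compared groups gave 0 on days -4 and 1 and 107 on day 7. The count of day -4 was 93 without baseline replicate 2, and 1 and 0 without unirradiated replicates 1 and 2, where Per2, Dbp and Bmal1 lost their calls. That of day 1 was 21, 438, 16 and 159 without baseline replicates 1 to 4, and 7 and 313 without unirradiated replicates 1 and 2. That of day 7 was 326, 372 and 1346 without baseline replicates 1, 3 and 4, and 138 and 57 without unirradiated replicates 1 and 2. On days 3 and 14 alternatives gave 0, apart from 2 and 1 on day 3 without unirradiated replicates 1 and 2, and 1 on day 14 without unirradiated replicate 2. Dbp on day 1 and Krtap1-5 and Sbk2 on day 7 kept their calls without each array.

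Irradiated skin with RTA-408 (n = 3) against unirradiated vehicle skin (n = 2) combined both exposures. The NRF2 list had 14, 11, 9, 12 and 3 of 37 genes higher in order of day (camera, adjusted p = 1.16e-19, 2.65e-21, 3.46e-05, 1.17e-05 and 0.284, and adjusted p = 3.75e-05, 3.52e-05, 0.0737, 0.0573 and 0.667 with an estimated correlation). Akr1b8 was at least 5.07 higher on day -4 (adjusted p = 2.31e-06) and higher by 5.70 ± 0.62 on day 1 (SE; adjusted p = 3.49e-07). Gsta1 was higher by 4.95 ± 0.46 on day 1 (SE; adjusted p = 2.4e-08). Abcb1b was at least 5.94 higher on day -4 and differed by 6.96 ± 0.44 on day 1 and 6.98 ± 0.44 on day 3 (SE). The p53 list had 11, 11, 9 and 8 of 27 genes higher on days -4, 1, 3 and 7 (camera, adjusted p = 5.21e-12, 4.31e-14, 2.75e-13 and 1.12e-08, and adjusted p = 9.73e-05, 3.75e-05, 4.87e-05 and 0.0013 with an estimated correlation). On day -4, 16 of 26 cell division genes were lower (camera, adjusted p = 7.63e-20, and adjusted p = 0.201 with an estimated correlation). On day 7, 11 of 23 interferon response genes and 16 of 24 macrophage and monocyte genes were higher (camera, adjusted p = 8.5e-16 and 2.85e-17, and adjusted p = 0.111 and 0.175 with an estimated correlation). On the same day, 10 of 15 wound and stress keratinocyte genes were higher (camera, adjusted p = 1.66e-11, and adjusted p = 0.0386 with an estimated correlation).

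For this comparison the counts were 586 higher and 483 lower on day -4, 214 and 134 on day 1, 316 and 215 on day 3, 826 and 363 on day 7, and 268 and 381 on day 14. With the labelling batch as a block 742, 314, 718, 1621 and 748 were called, and within a batch 188, 113, 181, 202 and 17. A fit of the compared groups alone gave 278, 75, 84 and 403 on days -4, 1, 3 and 14, and the replicate number as a block 81, 6, 1 and 170. The count of day -4 was 184 without RTA-408 replicate 3 and 115 and 119 without unirradiated replicates 1 and 2, and that of day 1 was 76 and 124 without RTA-408 replicates 1 and 3 and 161 and 169 without the unirradiated ones. On day 3 it was 169 without RTA-408 replicate 3 and 1201 and 38 without the unirradiated ones, and on day 7 it was 639 and 565 without RTA-408 replicates 1 and 3 and 562 and 109 without the unirradiated ones. On day 14 it was 256 and 183 without RTA-408 replicates 1 and 2 and 10 without unirradiated replicate 1.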

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

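The tests of explanations, the tests of lists between day -4 and later days, the settings that use labelling batches and the reading of the splits of the samples were chosen only after the results were seen, while the F-tests of change over the days and the comparison of baseline arrays with each other were planned.

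In the 6 baseline biopsies, 4 of 38 gene lists and 5 of 52 genes had 1 array far from the others, where chance alone gives about 1 in 20. The share of the whole range taken by the gap was 0.783 for hair shaft keratin genes (baseline replicate 4, mean 10.96, the others 14.42 to 15.38) and 0.902 for muscle genes (baseline replicate 2). It was 0.669 for fibroblast and 0.642 for collagen and extracellular matrix genes, with baseline replicate 4 highest at 13.30 and 13.66. Among genes, baseline replicate 4 stood apart for Gclc (0.692), Ifit1 (0.635), Krtap19-5 (0.725) and Krtap7-1 (0.776), and baseline replicate 5 for the kinase gene Sbk2 (0.719).

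The effect of RTA-408 changed over the days by the F-test for 3 features, among them Gstm1 and Gp2 (adjusted p = 0.0127 each). Between day -4 and later days, 304 list changes were tested, 86 were called and 3 of these with an estimated correlation, all 3 of the NRF2 list in the drug comparison on day 3 (0.00597), day 7 (0.000221) and day 14 (0.000325). The drug effect on this list was smaller on those days than on day -4. The injections ended on day 0.

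The effect of radiation changed over the days for 501 features. Among the genes named here, these were Sbk2 (adjusted p = 0.0025), Sprr1a (0.00603), Gpr15lg and Tmprss11d (0.0107 each), Ephx1 (0.0111), RT1-DMa (0.0183), Atp5po (0.028), Cyc1 (0.0288), Tnc (0.0339), Itgb4 (0.0395) and Krtap1-5 (0.0493).

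Inflammatory and immune lists were lower with RTA-408 than with vehicle on day 14. Without irradiated vehicle replicate 3, which is 1 rat, 0 of 8 such lists were still called lower, so this rat standing apart may account for the pattern. Both arms had the same batch mix, so blocking (8 of 8 still called lower) could not test the batch. A drug effect on inflammation stays open and was not shown by these calls.

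Hair shaft keratin genes were low in both unirradiated biopsies of day 7. The other 4 unirradiated arrays of labelling batch III had list means of at least 11.88, which argues against the batch as such, although calls of single genes were lost with that batch as a block (Krtap1-5, adjusted p = 0.222). Irradiated arrays filed under these labels would carry the p53 response, and 0 of 30 irradiated arrays had a p53 list mean as low as these 2, which argues against mislabelling. Fewer follicles in the biopsies would lower sebaceous gland genes too, and these were higher by 0.64. A resting phase of the hair cycle could be a candidate, and no biological explanation was tested.

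Muscle transcripts differed widely between biopsies of the same group. The list mean was 6.34 in baseline replicate 2 and 15.89 to 16.93 in the other baseline arrays. The range was 10.59 within the baseline arrays, all of batch I, which argues against labelling batch. The lowest later value of the same rat was 15.77, which argues against a lasting difference between rats. How much muscle the biopsies held was not tested, and no biological explanation was tested.

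The 6 irradiated rats can be split 3 against 3 in 10 ways, the real one included, too few for a share under 0.05. The numbers of splits as large below include the real one. For RTA-408 against vehicle the real split called 11 features on day -4 (highest other 65, with 2 splits as large), 17 on day 1 (highest other 1, with 1 as large), 1 on day 3 (highest other 2, with 3), 0 on day 7 (highest other 2, with 10) and 0 on day 14 (highest other 104, with 10). The mean of the 5 days gave 0 (highest other 1, with 10), the change over the days 3 (highest other 2, with 1) and the lists 45 (highest other 59, with 5). The split with 65 on day -4 puts both arrays of labelling batch II on one side. There the blocked count for the real split was 12 and the count within batch I was 5. The 65 and 104 point to a structure of the samples, whose cause was not tested for these splits.

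For the comparisons with baseline, 84 splits were possible. For the counts of features only 1 split, the real one, gave a count as large, a share of 0.0119. These splits treat the arrays as independent, although 2 of the 3 irradiated rats of each arm also gave a baseline array. From day 3 on the real split parts the arrays by labelling batch too, so it does not set treatment apart from the batch. With the batch as a block the counts of these days were 141 to 763. For irradiated vehicle the counts were 2486, 2255, 1980, 3242 and 3580, and the highest others 735, 700, 588, 655 and 3319. The split with 3319 joined irradiated vehicle replicates 2 and 3 of day 14 with baseline replicate 4. For irradiated RTA-408 they were 1343, 2542, 2246, 3661 and 2375, and the highest others 960, 1327, 891, 920 and 636. Chance cannot be excluded for the number of lists called: 83 against a highest other of 103 for irradiated vehicle (11 of 84 splits as large), and 89 against 109 for irradiated RTA-408 (7 of 84).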

How the results depend on the processing

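The settings that use labelling batches were chosen only after the data were seen, while all other settings in this part were planned. Of the counts under settings that change the method, 185 stayed within 1.5 times the value of the report and 82 did not. When arrays or rats were left out, 174 stayed within it and 95 did not. Single genes stayed on their side of the threshold in 7514 cases, were weaker in 852 and stronger in 64 under changed methods, and the numbers were 7177, 1097 and 67 with arrays left out. Gene lists stayed in 2200 cases, were weaker in 535 and reversed in 7 under changed methods, and with arrays left out the numbers were 2835, 344 and 19. Where no cause is named below, the cause was not tested.

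Renewed quantile normalization gave 7 features for RTA-408 against vehicle on day -4 and 1 on day 14. It left the median difference of every comparison within 0.1 and turned no called direction around. Leaving out the dimmest features gave 0 on day 3 and 1 on day 14 in the same comparison, and 139 for unirradiated skin against baseline on day 1. Here fewer features are tested, and on day 3 the lost feature, Gp2, is itself dim.

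Array weights gave 22, 34 and 7 for RTA-408 against vehicle on days -4, 1 and 14, and 3825 and 966 for irradiated against unirradiated vehicle on days -4 and 1. They gave 3735, 4079 and 3056 for irradiated vehicle against baseline on days -4, 1 and 3, and 2175, 4186 and 3608 for irradiated RTA-408 against baseline on days -4, 1 and 14. For unirradiated skin against baseline they gave 238, 221 and 1373 on days -4, 1 and 7, and for RTA-408 against unirradiated skin 2738 and 2069 on days -4 and 7. Changes over the days then numbered 7 for the drug and 2221 for radiation. The lowest weight, 0.219, was that of irradiated vehicle replicate 3 on day 14.

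The estimated correlation called 2 lists for RTA-408 against vehicle, 7 for irradiated against unirradiated vehicle, 5 for irradiated vehicle and 6 for irradiated RTA-408 against baseline, 0 for unirradiated skin against baseline and 9 for RTA-408 against unirradiated skin. With the preset correlation these were 45, 85, 83, 89, 60 and 95 of 190.

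A fit of the compared groups alone gave 0, 6 and 0 for RTA-408 against vehicle on days -4, 1 and 3. For irradiated against unirradiated vehicle it gave 2000, 220, 91, 855 and 0 in order of day. It gave 856 for irradiated vehicle against baseline on day 14, 552 for irradiated RTA-408 against baseline on day -4, and 0, 0 and 107 for unirradiated skin on days -4, 1 and 7. For RTA-408 against unirradiated skin it gave 278, 75, 84 and 403 on days -4, 1, 3 and 14.

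Rats give the only pairing in the labels, and replicate numbers denote different rats in different arms. Unirradiated replicate 2 is rat 318 up to day 3, then rat 317, so leaving it out on all days takes out both. Residuals of arrays of a rat had a median correlation of 0.0179 over 102 pairs, with 28 pairs above 0.1, and a consensus of 0.0067. Arrays that share a replicate number on a day had a median of -0.0302 over 35 pairs, with 8 above 0.1. The random rat block gave 17 features for the mean of the 5 days, fitted there to single arrays, and kept the other counts within 1.5 times. The fixed block of replicate numbers gave 0, 1 and 0 for RTA-408 against vehicle on days -4, 1 and 3, and 187, 78 and 26 for irradiated against unirradiated vehicle on days 1, 3 and 14. For RTA-408 against unirradiated skin it gave 81, 6, 1 and 170 on days -4, 1, 3 and 14.

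With the labelling batch as a block, irradiated vehicle against baseline gave 141, 518 and 560 features on days 3, 7 and 14, and irradiated RTA-408 against baseline 141, 763 and 246. The mean of the 5 days gave 26, fitted there to single arrays without a term for the rat. Unirradiated skin against baseline gave 114 on day 1 and 4 on day 7. From day 3 on no array of these groups is in the batch of the baseline. Within batch I, the fit gave 5 and 5 for RTA-408 against vehicle on days -4 and 1, 666 and 79 for irradiated against unirradiated vehicle, 986 and 1312 for irradiated vehicle against baseline, 284 for irradiated RTA-408 against baseline on day -4, 2 and 10 for unirradiated skin, and 188 and 113 for RTA-408 against unirradiated skin. Within batch III, it gave 0 on day 3 and 7 on day 14 for RTA-408 against vehicle, 113 and 124 for irradiated against unirradiated vehicle on days 3 and 7, and 181, 202 and 17 for RTA-408 against unirradiated skin on days 3, 7 and 14. These fits use fewer arrays.

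Leaving out 1 array at a time gave ranges in order of day. They were 0 to 11, 5 to 11, 1 to 2, 0 to 2 and 0 to 1344 for RTA-408 against vehicle, and 114 to 1516, 125 to 396, 32 to 957, 123 to 813 and 98 to 2962 for irradiated against unirradiated vehicle. They were 941 to 2868, 1265 to 3091, 1148 to 2652, 1831 to 3568 and 1594 to 4576 for irradiated vehicle against baseline, and 331 to 1864, 1444 to 3257, 1190 to 2867, 2478 to 3965 and 1405 to 2815 for irradiated RTA-408 against baseline. For unirradiated skin against baseline they were 0 to 93, 7 to 438, 0 to 2, 57 to 1346 and 0 to 1. For RTA-408 against unirradiated skin they were 115 to 1355, 76 to 346, 38 to 1201, 109 to 980 and 10 to 764. When a replicate number of an arm was left out on all days, or 1 baseline array, changes over the days ranged from 0 to 39 for the drug and from 74 to 838 for radiation, and the mean of the 5 days from 0 to 0. Lists ranged from 32 to 60, 69 to 93, 80 to 90, 82 to 93, 41 to 61 and 80 to 95 in the order of the comparisons above. Where 1 unirradiated array was left, it was assumed to vary like the other groups.

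The direction of 26 list results was reversed, given here with the adjusted p after the turn and, where a replicate number was left out on all days, with the range of adjusted p over all such replicates. Without RTA-408 replicate 1, muscle genes on day -4 turned against vehicle (0.00273, range 1.6e-07 to 0.941) and against baseline (0.914, range 8.19e-14 to 0.914), and without RTA-408 replicate 2 fatty acid and sterol synthesis turned against vehicle on day 1 (0.0417, range 4.82e-09 to 0.172). Without irradiated vehicle replicate 3, the drug effect on day 14 turned for inflammatory (0.259, range 3.55e-08 to 0.259), interferon (0.138, range 4.91e-07 to 0.138) and antigen presentation genes (0.831, range 5.56e-06 to 0.831). Without unirradiated replicate 1, unirradiated skin against baseline turned for hair shaft (0.694, range 8.35e-10 to 0.694) and muscle genes (0.49, range 1.6e-16 to 0.49) on day 1. On day 3 it turned for cell division (0.176, range 3.18e-06 to 0.206) and DNA replication (0.242, range 8.28e-07 to 0.242), and on day 14 for oxidative phosphorylation (0.396, range 3.3e-06 to 0.396). Without unirradiated replicate 2, it turned for fibroblast (0.698, range 4.19e-07 to 0.698) and endothelium genes (0.983, range 2.2e-06 to 0.983) on day 3 and for cell division (0.909, range 2.75e-08 to 0.909) and DNA replication (0.502, range 7.61e-08 to 0.502) on day 7. Leaving out this replicate number, whose arrays come from different rats up to day 3 and later, also turned cell division on day 7 (0.54, range 2.09e-06 to 0.54) and oxidative phosphorylation on day 14 (0.87, range 1.87e-05 to 0.87) for irradiated against unirradiated vehicle, and DNA replication on day 3 (0.487, range 0.000182 to 0.487) and cell division on day 7 (0.718, range 6.69e-07 to 0.718) for RTA-408 against unirradiated skin. The labelling batch as a block turned DNA replication for irradiated RTA-408 against baseline on day 14 (0.865). In unirradiated skin against baseline this block turned cell division (0.00258) and DNA replication (0.413) on day 3, cell division (0.45) and antigen presentation (0.71) on day 7, and oxidative phosphorylation (0.0432) and immediate early genes (0.954) on day 14.

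A group at the level of the negative controls gives a bound and not a difference.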

Other observations

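The test for labelling batch in this part was chosen only after the data were seen, and the values below belong to no comparison. Over all 46 arrays the first 3 principal components held 38.2, 14.0 and 10.3 percent of the variance. An F-test for labelling batch beside the groups called 452 of 23188 features. Muscle list means were low in 6 arrays, with 6.34, 6.50 and 7.93 given above. Irradiated vehicle replicate 2 of day -4 had 11.16. On day 14, unirradiated replicate 1 had 12.12 and irradiated vehicle replicate 3 had 12.32.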
